A study of Homo sapiens with 18 samples.

How the data were processed

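The study set the loss of cohesin against the loss of CTCF in human embryonic kidney cells (HEK293T, a line carrying adenoviral genes and the SV40 large T antigen). Cohesin is a ring of SMC1A, SMC3, RAD21 and a STAG protein that holds DNA segments together, and CTCF is a zinc finger protein that binds DNA and marks many positions where cohesin is found. For cohesin, per the labels, the line RAD21cv carried a transgene that was switched on with 2 µg/mL doxycycline for 3 days, after which the cells received a plasmid for the protease TEV or for the protease HRV and were harvested 24 hours later. Which of the proteases cleaves the engineered RAD21 is not given in the sources used here, so this comparison is written as TEV against HRV and the tests of the difference between the responses to protease and to siRNA, for genes, gene lists, domains and borders, were made in both orientations. For CTCF, HEK293T cells not of that line received a CTCF siRNA (siCTCF) or a control siRNA (siControl) and were harvested after 48 hours. Each of these 4 groups had 2 Hi-C libraries (chromatin cross-linked and cut with HindIII, so that pairs of joined fragments report contacts) and 2 libraries of polyadenylated RNA made with a strand-specific protocol, which gave 8 libraries per assay. Of the 18 samples, 2 ChIP-seq samples whose labels name different proteases in different fields were put in no group and were not analysed here. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

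Per the submitters' processing notes, reads were aligned to the human build hg18 and the tools used were BWA, Bowtie, TopHat and Picard. Their versions, their roles, the gene annotation and the strand used for counting are not given in the sources used here. The deposited RNA files held, for 23650 gene models with hg18 coordinates, a whole-number read count and an RPKM value. The RPKM values (reads per kilobase of gene, scaled to the size of the library) were computed by the authors, and genes without reads stood at 0.05, so that a small constant had been added. A repeated symbol was carried by 611 of the gene models. The deposited Hi-C values were a contact signal for each pair of 40-kb bins on 1 chromosome, with decimals and never below 0. Sums of this signal were similar for chromosomes of different length, so the authors had normalized it, by a method not given in the sources used here. The signal is therefore relative, its read depth is unknown, and loss or gain of contacts over a whole chromosome or genome cannot be read from it. In 7 libraries the pairs reached 10 Mb. In HRV replicate 2 they reached 1 Mb, so distances up to 1 Mb were used for all libraries. Coordinates are 1-based and on hg18.

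Gene counts were tested with edgeR (version 4.0.16, quasi-likelihood test, TMM scaling, two-sided) in a fit of the 4 groups to all 8 libraries, over the 12621 gene models with a mean RPKM of at least 1. Adjusted p-values are Benjamini-Hochberg values, and the threshold was 0.05. The design fixed before the data were examined named limma on log2(RPKM + 1) for RPKM files and edgeR for files with counts. The files held both, so edgeR gave the main values, while limma (version 3.58.1) and DESeq2 (version 1.42.0) served as alternatives. Log2 fold changes are from edgeR and levels are the authors' RPKM, given as mean ± SD of 2 libraries. Replicate libraries differed by more than counting noise, with a chi-square per degree of freedom of 86 for TEV, 117 for HRV, 5.35 for siControl and 3.11 for siCTCF, so none were duplicates. The biological coefficient of variation was 0.113. Count totals ranged from 27445883 to 90338538 per library. Because the counting strand is unknown, genes that overlap another gene, on either strand, are named as uncertain, as are members of near-identical families.

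Before the data were examined, 33 gene lists were fixed, covering chromatin organisers, developmental gene clusters, the cell cycle, stress and signalling responses, basic cell functions and markers of other cell types. The 29 lists with at least 3 tested members were compared with all other genes by camera (limma) with a preset correlation of 0.01 between members, and again with an estimated correlation, adjusted over the lists within a comparison. Members past the threshold were counted over all genes tested and adjusted over the list alone. The genes named in the text were, by a rule fixed before the data were examined, the targeted gene, the 10 largest rises and the 10 largest falls past the threshold without overlap between groups, up to 4 members past the threshold from each list with an adjusted p under 0.05, and the 5 largest differences between the arms in each direction. For Hi-C these were the 3 largest rises and falls of domains and of borders, and the domains holding the HOX clusters, the protocadherin clusters and IGF2 with H19. Some items that the rule names are not reported here. No gene passed for TEV against HRV, so in that comparison every gene other than RAD21 was chosen after its values were seen.

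Hi-C maps were analysed with Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3). Each value was divided by the mean of its library, chromosome and distance (observed over expected). Borders were minima, with a prominence of at least 0.2 on the log2 scale, of the mean contacts in a square of 400 kb on either side, in the mean map of all 8 libraries weighted equally, with at least 80% of the square listed. Domains were the intervals between neighbouring borders, from 160 to 2400 kb. Inside each domain, and across each border, the summed values were divided by the summed expected values, so that near pairs weigh most. Sums across a border covered up to 400 kb on either side, within the domains that meet there. The log2 of these ratios was tested with limma (trend) in a fit of all 8 libraries. Without a test, because 2 against 2 libraries allow no exact permutation p under 0.33, the share of contacts 40 to 160 kb apart, the share of borders found within 1 bin in another library and the ratio of contacts within to between compartments were computed per library. Compartments came from the mean map of the 7 libraries that reached 10 Mb, for pairs up to that distance. They were the side, highest or lowest 30% of 200-kb bins, of its eigenvector, among the first 3, that followed gene density most closely. For each library, the eigenvector closest to that of the mean map, among its first 3, was used with its sign matched. For the figures matplotlib 3.10.9 was used.

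The tests were tried on simulated data made from the real libraries, those of single genes with 200 genes changed by known amounts and those of Hi-C with 100 features changed by each of 2 amounts. edgeR recovered 13.4%, 92.5% and 100% of genes changed by 0.5, 1 and 2 on the log2 scale for TEV against HRV, with 9 false calls among 146, and 17.9%, 80.6% and 95.5% for siCTCF against siControl, with 10 false calls among 139. For each gene these simulations gave all libraries the same dispersion. Real replicates differed more in RAD21cv cells (SD of the log2 difference 0.329 and 0.337) than in the siRNA groups (0.18 and 0.154). The recovery and false calls for genes therefore may not hold for the real libraries. In the Hi-C simulation for TEV against HRV, limma recovered 28% of domains changed by 0.1 and 88% of those changed by 0.2, with 44 false calls among 160. For siCTCF against siControl it recovered 8% and 97%, with 0 false calls among 105. Of borders it recovered 6% and 55% at these sizes for TEV against HRV, with 10 false calls among 71, and 0% and 37% for siCTCF against siControl, with 0 false calls among 37. Of 29 simulated lists of 25 genes, 10 were shifted by 0.3, and camera recovered 10 of these with 0 false calls among the rest, for either comparison and with either correlation. The simulated genes varied independently, so this does not test how camera treats correlated genes. In these simulations the Hi-C test of domains was thus too lenient for the RAD21cv line, and most features changed by 0.1 were missed in the siRNA libraries. Each group was simulated with its own spread, while the fit shared its spread over the groups. Noise was drawn independently for each library, whereas real same-numbered TEV and HRV libraries deviated alike (correlation 0.69 inside domains). The leniency therefore may not carry over to the real comparison. Its cause was not tested further. The alternatives were other scalings, filters, pseudocounts, insulation windows and tools, iterative correction (ICE) and quantile normalization of the Hi-C values, the replicate number as a block, the 4 libraries of a comparison alone, and leaving out each library in turn.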

Results

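Chromosome contacts and messenger RNA were measured in human HEK293T cells after interference with cohesin and with CTCF. RAD21cv cells expressed an engineered form of the cohesin subunit RAD21 and received the protease TEV or HRV, and HEK293T cells not of that line received a CTCF siRNA or a control siRNA. Each of the 4 groups had 2 Hi-C and 2 RNA libraries. The total counts of the RNA libraries were 64882171 and 77693702 for TEV, 90338538 and 69616100 for HRV, 28186885 and 27445883 for siControl, and 29096869 and 31632023 for siCTCF. The 10 most abundant genes took 4.25% to 4.91% of the counts of a library. Replicates were closer in the siRNA groups than in RAD21cv cells. The SD across genes of the log2 difference between replicates was 0.18 for siControl and 0.154 for siCTCF, but 0.329 for TEV and 0.337 for HRV. Same-numbered TEV and HRV libraries differed by less, 0.262 for replicate 1 and 0.205 for replicate 2. Among pairs of 40-kb bins up to 1 Mb apart, 96.37% to 99.27% had a Hi-C value above 0.

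The first question was which genes differed between RAD21cv cells given TEV and those given HRV. RAD21 itself (chromosome 8, 117927353 to 117956286, minus strand) stood at 461 ± 53.8 RPKM (SD, n = 2; 423 and 499) with TEV and 540 ± 40.6 RPKM (568 and 511) with HRV. This was about an order of magnitude above the 42.3 ± 0.937 RPKM of siControl and 46.8 ± 1.35 RPKM of siCTCF cells, which were not of the RAD21cv line. The TEV to HRV difference in RAD21 mRNA did not pass (log2 −0.17, SE 0.09, edgeR adjusted p = 0.803), and mRNA does not report cleavage of the protein. MYC, a transcription factor that drives cell growth (chromosome 8, 128817496 to 128822862), had the smallest adjusted p of all genes. Its level was 21.2 ± 1.52 RPKM with TEV against 40.2 ± 5.06 RPKM with HRV (log2 −0.86, SE 0.09, edgeR adjusted p = 0.0948), while siControl cells had 38.2 ± 2.57 and siCTCF cells 35.5 ± 1.86 RPKM. The cohesin subunit gene STAG1 stood at 7.97 ± 0.297 against 12.5 ± 0.754 RPKM (log2 −0.59, SE 0.08, edgeR adjusted p = 0.147).

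Among single genes, edgeR called 0 of 12621 for TEV against HRV, with 820 at an unadjusted p under 0.05. DESeq2 called 52, 32 higher and 20 lower, and limma 0. DESeq2 gave adjusted p = 1.49e-13 for MYC and 4.26e-06 for STAG1. The TEV and HRV libraries did not overlap for 3137 genes (24.9%), where chance gives 33.3%. The edgeR p-values draw on the closer siRNA replicates. With the 4 RAD21cv libraries fitted alone edgeR called 0 genes, and 210 had an unadjusted p under 0.05. With all 8 libraries and the replicate number as a block within each cell line it called 22, though the labels give no pairing. Without a filter on low values edgeR called 5 genes, and without TEV replicate 2 or without HRV replicate 2 it called 3. Other genes with low p-values, none past the threshold, included HAP1, which encodes huntingtin-associated protein 1 (log2 1.05, 2.50 ± 0.198 against 1.28 ± 0.0207 RPKM, edgeR adjusted p = 0.106), and IRS4, an insulin receptor substrate (log2 −0.74, 84.7 ± 4.80 against 147 ± 8.31 RPKM, adjusted p = 0.128). CCNE2, which encodes cyclin E2 of the G1/S transition, stood at 13.9 ± 1.51 against 8.02 ± 0.127 RPKM (log2 0.86, adjusted p = 0.128).

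As groups, several fixed lists stood apart from the other genes in this comparison. Of 25 ribosome biogenesis genes and MYC targets, 23 were lower with TEV, with a median log2 of −0.22 (camera adjusted p = 5.23e-10; adjusted p = 0.327 with an estimated correlation). None passed over all genes and 1, MYC, was lower when adjusted over the list alone. HRV replicate 1 exceeded HRV replicate 2 by a median of 0.26 in this list, as large as the shift itself, and TEV replicates differed by 0.14. GNL3 (−0.27), POLR1B, a subunit of RNA polymerase I (−0.28), and PPAN (−0.34) were members. Of 24 p53 targets, 19 were higher, with a median of 0.398 (camera adjusted p = 2.11e-09; adjusted p = 0.327 with an estimated correlation). Here 0 passed over all genes and 5 were higher adjusted over the list alone. These 5 were the cell cycle inhibitor CDKN1A (log2 1.02, SE 0.23; 25.6 ± 2.23 against 13.1 ± 4.58 RPKM), the p53 ubiquitin ligase MDM2 (0.54), ZMAT3 (0.57), the death receptor gene TNFRSF10B (0.50) and C12orf5 (0.40). HRV replicates themselves differed in this list, with a median log2 of −0.52 for replicate 1 minus replicate 2, against 0.09 for TEV.

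Among the HOX clusters of homeobox genes, which pattern the body axis, the HOXA, HOXB and HOXC lists stood above the other genes with a preset correlation and did not pass with an estimated one. All 11 tested HOXA genes were above 0 (median 0.364, camera adjusted p = 1.36e-07; adjusted p = 0.327 with an estimated correlation), with 0 past the threshold over all genes and 0 adjusted over the list alone. HOXA7 (0.60), HOXA10 (0.52) and HOXA11 (0.51) were among them. All 9 tested HOXB genes were above 0 (median 0.413, camera adjusted p = 4.7e-06; adjusted p = 0.327 with an estimated correlation), again with 0 over all genes and 0 adjusted over the list alone, led by HOXB5 (0.73) and HOXB4 (0.68). All 8 tested HOXC genes were above 0 (median 0.339, camera adjusted p = 1.13e-07; adjusted p = 0.29 with an estimated correlation). Over all genes 0 passed, and 5 were higher adjusted over the list alone, namely HOXC5 (0.46), HOXC6 (0.46), HOXC8 (0.32), HOXC9 (0.76) and HOXC13 (0.35). TEV replicates differed in HOXA, HOXB and HOXC by medians of 0.55, 0.6 and 0.3 (replicate 1 minus 2), and HRV replicates by 0.06, −0.03 and −0.09. Of 7 tested HOXD genes 4 were above 0 and 3 below, and the list missed the threshold (camera adjusted p = 0.0561; adjusted p = 0.529 with an estimated correlation).

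Replication-dependent histone genes, whose normal transcripts lack polyA tails, were higher in 20 of 21 with a median of 0.527 (camera adjusted p = 0.00371; adjusted p = 0.754 with an estimated correlation), with 0 over all genes and 0 adjusted over the list alone. HIST1H1D (0.93) and HIST1H2AM (0.85, SE 0.41) were examples. TEV replicate 1 exceeded TEV replicate 2 by a median of 1.47 in this list, more than TEV exceeded HRV. Immediate early genes, induced within an hour of growth signals, were lower in 10 of 14 (median −0.405, camera adjusted p = 3.97e-05; adjusted p = 0.283 with an estimated correlation). Over all genes 0 passed, and MYC, DUSP1 (−0.50) and DUSP2 (−0.56) were the 3 lower adjusted over the list alone, while ZFP36 stood at 0.65. Of 5 tested cohesin subunits 4 were lower (median −0.092, camera adjusted p = 8.59e-04; adjusted p = 0.283 with an estimated correlation), with 0 over all genes and 1, STAG1, adjusted over the list alone. STAG2 and SMC3 both stood at −0.09.

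Smaller shifts were measured in other lists. Oxidative phosphorylation genes were higher in 30 of 33 (median 0.104, camera adjusted p = 0.00179; adjusted p = 0.75 with an estimated correlation), mitosis and G2/M genes in 24 of 33 (median 0.088, adjusted p = 0.00476; adjusted p = 0.327 with an estimated correlation) and heat shock genes in 11 of 13 (median 0.138, adjusted p = 0.0347; adjusted p = 0.697 with an estimated correlation). In each of these 0 passed over all genes and 0 adjusted over the list alone; mitotic members included NUSAP1 (0.33) and CDC25C (0.34). S phase genes were higher in 18 of 30 (median 0.049, camera adjusted p = 0.0162; adjusted p = 0.75 with an estimated correlation), with 0 over all genes and CCNE2 alone higher adjusted over the list alone. Imprinted genes were higher in 7 of 9 (median 0.114, adjusted p = 0.0433; adjusted p = 0.327 with an estimated correlation), with 0 by either count; IGF2R stood at 0.23 and PHLDA2 at 0.44. Replicates differed by as much or more in several of these lists. For replicate 1 minus replicate 2, the medians in TEV and then HRV were 0.34 and −0.01 for oxidative phosphorylation, 0.2 and 0.11 for S phase, −0.17 and −0.24 for heat shock and −0.14 and −0.29 for neuronal genes. Neuronal genes were higher in 8 of 10 (median 0.078, adjusted p = 0.0447; adjusted p = 0.327 with an estimated correlation), with 0 over all genes and TUBB3 (0.72) higher adjusted over the list alone. The other 15 lists had adjusted p from 0.0561 to 0.992. With an estimated correlation the 14 called lists had adjusted p from 0.283 to 0.754, so none of these calls held. Unfolded protein response genes had a median of 0.009 but a mean of −0.072 and a downward test, and NF-kB genes a median of −0.13, a mean of 0.02 and a downward test. Markers of other cell types could hardly be scored, with 1 of 9 fibroblast, 2 of 12 blood and 0 of 9 liver markers tested, and the same held for the clustered protocadherins with 1 of 53. Of the epithelial and keratinocyte markers 3 were tested (adjusted p = 0.861).

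**Figure D1:**
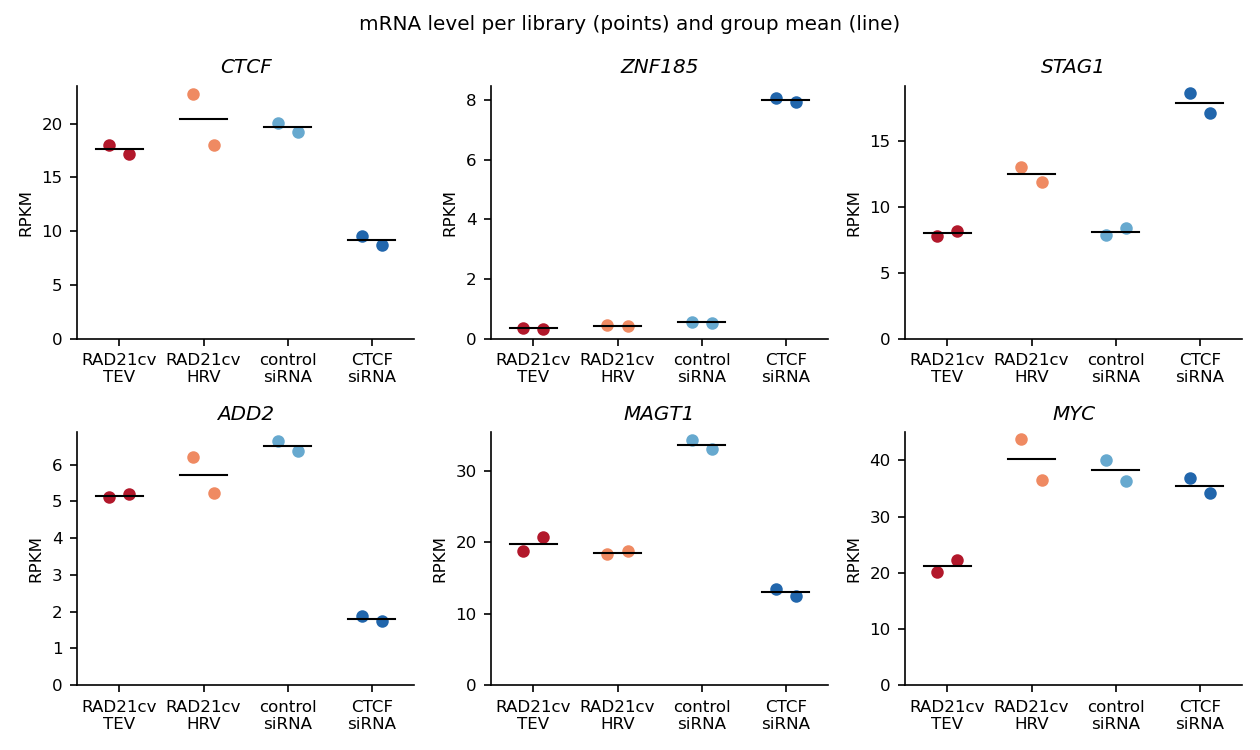
RPKM (vertical axis) of CTCF, ZNF185, STAG1, ADD2, MAGT1 and MYC in the 4 groups (horizontal axis), with a point for each library and a line at the group mean. ZNF185 is at 8.01 RPKM with the CTCF siRNA against 0.545 in control cells, STAG1 is at 17.9 against 8.11 in those groups and at 7.97 with TEV against 12.5 with HRV, and MYC is at 21.2 with TEV against 40.2 with HRV.

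The next comparison asked which genes changed with the CTCF siRNA. The libraries used here do not report CTCF protein. CTCF mRNA (chromosome 16, 66153810 to 66230589, plus strand) fell from 19.7 ± 0.613 (20.1 and 19.2) to 9.16 ± 0.585 RPKM (9.58 and 8.75), a log2 change of −1.10 (SE 0.10, edgeR adjusted p = 0.00382). RAD21cv cells had 17.6 ± 0.568 RPKM with TEV and 20.4 ± 3.38 with HRV. The largest response was that of ZNF185, a LIM domain protein gene (chromosome X, 151833641 to 151892681, plus strand), which rose from 0.545 ± 0.012 to 8.01 ± 0.108 RPKM (log2 4.01, SE 0.12, edgeR adjusted p = 9.61e-06). Of the 14 other tested entries within 500 kb of it, none had a log2 change above 0.1. The centrin gene CETN2 (chromosome X, 151746526 to 151749957, minus strand), named after its value was seen, fell (log2 −0.82, SE 0.13, edgeR adjusted p = 0.0482), and GABRA3 stood at −0.34 (adjusted p = 0.766). STAG1 (chromosome 3, 137538688 to 137953935, minus strand) rose from 8.11 ± 0.361 to 17.9 ± 1.03 RPKM (log2 1.15, SE 0.08, adjusted p = 0.00233). ADD2, which encodes the membrane skeleton protein beta-adducin (chromosome 2, 70742723 to 70848883, minus strand), fell from 6.50 ± 0.174 to 1.80 ± 0.0962 RPKM (log2 −1.88, SE 0.09, adjusted p = 0.000172).

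In all, 71 genes passed with the CTCF siRNA, 21 higher and 50 lower, with 1034 at an unadjusted p under 0.05. DESeq2 called 216 and limma 54. The groups did not overlap for 7416 genes (58.8%; chance gives 33.3%), nor for any of the 71. Among the other falls, MAGT1, a gene for magnesium transport and protein glycosylation (chromosome X, 76968517 to 77037721, minus strand), went from 33.7 ± 0.861 to 13 ± 0.693 RPKM (log2 −1.37, SE 0.09, edgeR adjusted p = 0.000897). RAD21cv cells had 19.8 and 18.5 RPKM. TMC7 (log2 −1.57, 1.42 to 0.513 RPKM), the ciliary gene CC2D2A (−1.31, 1.46 to 0.618 RPKM), the mitochondrial protein gene NLRX1 (−1.24, 3.80 to 1.63 RPKM), ZBTB39 (−1.21, 4.10 to 1.80 RPKM) and FAM131C (−1.67) also fell, with edgeR adjusted p between 0.00382 and 0.0363. HMOX1, the inducible haem oxygenase, fell from 8.08 ± 0.0226 to 3.29 ± 0.205 RPKM (log2 −1.30, SE 0.21, adjusted p = 0.0475). Other falls are uncertain because the gene overlaps another on the opposite strand, B4GALNT1 (−1.47, SLC26A10) and LOC100130776 (−1.39, AGAP2).

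Several of the rises were in overlapping genes and are uncertain for the same reason. FDXACB1 rose from 2.16 to 6.0 RPKM (log2 1.5, edgeR adjusted p = 0.00302) and lies opposite C11orf1. C17orf49 rose from 12.2 to 29.9 RPKM (log2 1.31, adjusted p = 0.00302) and overlaps a readthrough gene with RNASEK and, on the other strand, MIR497HG. LOC440356 (log2 2.10, 0.612 ± 0.0872 to 2.47 ± 0.188 RPKM) lies among the near-identical SLX1 and SULT1A copies of chromosome 16. LOC100506649 (1.48) is antisense to PXN, LOC100505549 (1.11) lies opposite ATP8B1, C12orf26 (1.04) opposite CCDC59 and ZBED3 (0.96) opposite LOC728723, and LOC100132273 (1.01) completes the 10 largest rises. With the 4 siRNA libraries fitted alone, so that the larger spread of the RAD21cv libraries did not enter, edgeR called 2207 genes. In the fit of all 8 libraries, where the larger spread of the RAD21cv libraries enters, the count of 71 fell when any siRNA library was left out. It was 3 without siControl replicate 1, 4 without siControl replicate 2, 3 without siCTCF replicate 1 and 2 without siCTCF replicate 2, but 118 without HRV replicate 1 or without HRV replicate 2.

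Of the fixed lists, 4 of 29 stood apart with the CTCF siRNA. Ribosomal protein genes were higher in 51 of 52 (median 0.163, camera adjusted p = 1.77e-09; adjusted p = 0.912 with an estimated correlation), with 0 over all genes and 0 adjusted over the list alone. For replicate 1 minus replicate 2, medians in this list were 0.1 in siControl and 0.07 in siCTCF, and 0.22 with TEV and −0.23 with HRV. Among its members RPL12 stood at 752 RPKM in control and 1030 in siCTCF cells (log2 0.46, edgeR adjusted p = 0.221), and RPL34 at 0.35. Cohesin subunits were higher in 4 of 5 (median 0.15, camera adjusted p = 1.02e-05; adjusted p = 0.211 with an estimated correlation). STAG1 was the 1 subunit past the threshold over all genes and also adjusted over the list alone, and STAG2 (0.19), RAD21 (0.15) and SMC1A (−0.05) did not pass. Oxidative phosphorylation genes were higher in 25 of 33 (median 0.121, adjusted p = 0.00813; adjusted p = 0.912 with an estimated correlation) and mitosis and G2/M genes in 24 of 33 (median 0.083, adjusted p = 0.0473; adjusted p = 0.912 with an estimated correlation), both with 0 over all genes and 0 adjusted over the list alone. CYCS (0.25), CDK1 (0.32) and CENPA (0.27) were examples. The other 25 lists had adjusted p from 0.0853 to 0.951, among them p53 targets (0.701), ribosome biogenesis (0.188), HOXA (0.495), HOXB (0.511), HOXC (0.951) and HOXD (0.165). In the last, 7 of 7 genes were above 0 with a median of 0.162.

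Within lists that did not pass, CTCF fell and ZBTB33, a methyl-DNA binding protein gene, was higher by 0.35 adjusted over the list alone among CTCF and its partners, where over all genes only CTCF passed. That list had a median of 0.042 but a mean of −0.083 and a downward test. The matrix cross-linking enzyme gene LOX (0.71) was higher, and KRT8 (−0.69) lower, adjusted over the list alone. TGFB1 fell over all genes (log2 −0.91, edgeR adjusted p = 0.0475) and adjusted over the list alone. Median, mean and test also differed in sign for immediate early genes (−0.014, −0.081, upward) and HOXC (0.008, −0.009, downward). The glucose-responsive gene TXNIP, which overlaps entries on both strands, rose from 6.59 to 12.6 RPKM (log2 0.94, SE 0.10, edgeR adjusted p = 0.013), and in the protease comparison it stood at 9.83 against 6.76 RPKM (log2 0.60, adjusted p = 0.342).

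Whether the protease and siRNA responses differed was tested as the TEV minus HRV change less the siCTCF minus siControl change. STAG1 had opposite signs in the arms and differed by −1.74 (SE 0.12, edgeR adjusted p = 0.00199). ZNF185 (−4.35, adjusted p = 6.12e-05), ADD2 (1.78, adjusted p = 0.00199), TMC7 (1.55, adjusted p = 0.0412), MAGT1 (1.52, adjusted p = 0.00406), CC2D2A (1.42, adjusted p = 0.0434) and NLRX1 (1.28, adjusted p = 0.0412) responded to the CTCF siRNA and differed between the arms, as did the uncertain FDXACB1 (−1.82, adjusted p = 0.0121), LOC440356 (−2.47), C17orf49 (−1.42) and C12orf26 (−1.36). In all 15 genes passed, 9 higher and 6 lower, with 1166 at an unadjusted p under 0.05, but 3, 3, 3 and 2 without siControl replicate 1, siControl replicate 2, siCTCF replicate 1 and siCTCF replicate 2, 8 without TEV replicate 1 and 64 without HRV replicate 2. With limma 9 passed (2 higher, 7 lower), and 14 after quantile normalization (6 higher, 8 lower). With the protease difference taken as HRV minus TEV, 13 passed, 10 higher and 3 lower, again including ZNF185 (−3.68), ADD2 (1.98), MAGT1 (1.23), TMC7 (1.58) and C17orf49 (−1.20), and also CTCF (1.26), MYC (0.96) and TXNIP (−1.54). STAG1 did not pass in that orientation (−0.56, edgeR adjusted p = 0.233). Cell line, agent and time after transfection all differ between the arms.

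Of the lists, 7 of 29 differed between the arms with the protease difference taken as TEV minus HRV. These were the cohesin complex (camera adjusted p = 1.39e-07; adjusted p = 0.114 with an estimated correlation), ribosome biogenesis and MYC targets (4.32e-07; adjusted p = 0.867 with an estimated correlation), p53 targets (1.27e-04; adjusted p = 0.867 with an estimated correlation), ribosomal proteins (9.7e-04; adjusted p = 0.867 with an estimated correlation), HOXC (0.00249; adjusted p = 0.867 with an estimated correlation), immediate early genes (0.0261; adjusted p = 0.661 with an estimated correlation) and HOXA (0.0347; adjusted p = 0.867 with an estimated correlation). With HRV minus TEV 14 lists differed, 6 of these 7 among them but not the cohesin complex (camera adjusted p = 0.23), and 0 with an estimated correlation. The p53, HOXA and HOXC lists then differed downward and not upward, while the difference for ribosomal proteins was downward in either orientation (medians −0.136 and −0.197). Replicates of the RAD21cv line differed by more in the ribosomal list, by medians of 0.22 with TEV and −0.23 with HRV (replicate 1 minus 2). With edgeR no gene was called in both arms, which could hardly be otherwise with 0 genes called for TEV against HRV. With DESeq2 there were 2, TXNIP, higher in both (0.157 expected for independent lists, Fisher's exact p = 0.146), and STAG1, lower with TEV and higher with the CTCF siRNA (0.0982 expected, p = 0.0939). Across genes, which are not independent replicates, the log2 changes of the arms correlated at r = −0.088 (Spearman −0.113), with no library in common.

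Hi-C was first used to ask how contacts spread over distance. In siCTCF libraries the share of contacts 40 to 160 kb apart, among those up to 1 Mb, was 37.658 ± 0.122% (SD, n = 2) against 39.23 ± 0.183% in siControl libraries. The difference of −1.572 points exceeded the range within either group and had the same sign on 23 of 23 chromosomes (−2.346 to −1.157). With TEV the share was 39.085 ± 0.199%, against 40.595 ± 1.032% with HRV. This difference of −1.51 points was also negative on 23 of 23 chromosomes but was hardly larger than the 1.46 points between the HRV libraries, and it was −0.78 points without HRV replicate 2. With adjacent bins left out it was −0.615 points, while the siCTCF difference was then −1.277 points. Within 10 Mb, the 40 to 160 kb share was 23.379% with the CTCF siRNA, a difference of −1.522 points, with 52.844% against 51.659% between 200 kb and 2 Mb and 23.778% against 23.44% from 2 to 10 Mb. No test was made, since 2 against 2 libraries allow no exact permutation p under 0.33. The agreement of chromosomes is not further evidence for either comparison, because chromosomes of a library are not independent. HRV replicate 2 also exceeded HRV replicate 1 on every chromosome, as did siCTCF replicate 1 siCTCF replicate 2. The TEV and the siControl replicates differed in sign between chromosomes.

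**Figure D2:**
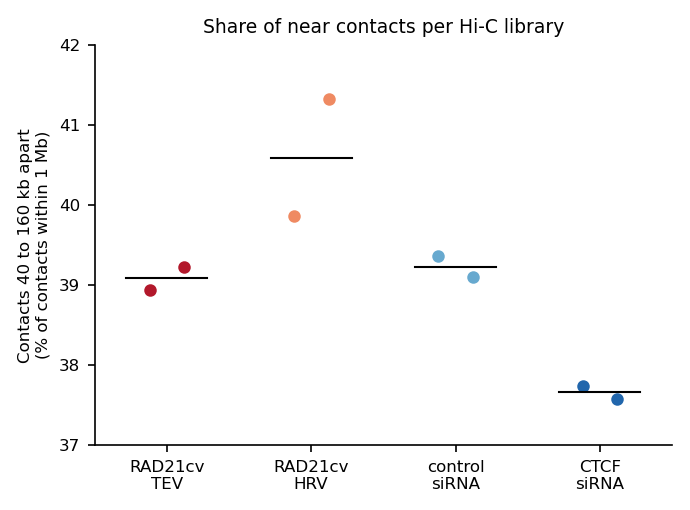
Share of Hi-C contacts that join bins 40 to 160 kb apart, in percent of contacts up to 1 Mb (vertical axis, drawn from 37% to 42%), for the 4 groups (horizontal axis), with a point for each library. The siCTCF libraries, at 37.744 and 37.571%, lie below the siControl libraries at 39.36 and 39.101%, while the HRV libraries, at 39.865 and 41.325%, differ by nearly as much as TEV and HRV do.

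Domains of frequent contact were then compared. Over the 8 libraries 2412 domains were found, from 320 to 2400 kb long with a median of 920 kb, which held 79.6% of the autosomes and X, and 2291 borders separated neighbouring domains. Contacts inside domains were lower, and contacts across borders higher, in siCTCF than in siControl libraries. Inside, 377 domains passed (limma, adjusted p under 0.05), 79 higher and 298 lower, the median log2 change was −0.034 and 32.6% of domains were above 0. Across, 443 borders passed, 377 higher and 66 lower, with a median of 0.047 and 65.9% above 0. The median value inside was 0.059 in both siCTCF libraries against 0.098 and 0.1 in siControl, and across borders −0.366 and −0.357 against −0.411 and −0.405. Quantile normalization, which removes a shift common to all domains, left 573 domains (274 higher, 299 lower) and 569 borders (276 higher, 293 lower), with a median across borders of −0.006. Without division by expected contacts 846 domains passed (51 higher, 795 lower). Without siControl replicate 1 or 2, or without siCTCF replicate 1 or 2, limma called 0 domains, and borders came to 50 and 120 without these siControl libraries and to 110 and 98 without these siCTCF libraries. Without HRV replicate 1 or 2 it called 741 and 730 domains and 676 and 677 borders. With the 4 siRNA libraries fitted alone it called 1610 domains.

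Of the domains that gained contacts with the CTCF siRNA, the largest change was on chromosome X, 47800001 to 48320000 (log2 0.269, SE 0.062, limma adjusted p = 0.026), which holds SSX genes, EBP and RBM3. Another gain was on chromosome 6, 32920001 to 34240000 (0.217, SE 0.05, adjusted p = 0.0273), in the major histocompatibility complex with HLA class II genes, TAP1 and BRD2. The largest losses were on chromosome 22, 26760001 to 27280000 (−0.299, SE 0.058, adjusted p = 0.0177), inside a region with TTC28, chromosome 1, 74960001 to 75440000 (−0.236, adjusted p = 0.0383), with CRYZ, TYW3 and LHX8, and chromosome 9, 87600001 to 88160000 (−0.231, SE 0.033, adjusted p = 0.012), with NAA35, GOLM1, ISCA1 and ZCCHC6. The domain with HOXA13, chromosome 7, 27200001 to 28120000, lost contacts (−0.114, SE 0.023, adjusted p = 0.0197). In the domains named on X and chromosomes 6, 22 and 1, both RAD21cv groups, given no CTCF siRNA, lay nearer to siCTCF than to siControl. On X the means were 0.702 with TEV, 0.751 with HRV, 0.72 in siCTCF and 0.451 in siControl. On chromosome 9 and in the HOXA13 domain TEV lay nearer to siControl and HRV nearer to siCTCF. The HOXB domains (−0.009 and 0.021), the HOXC domain (0.095, adjusted p = 0.246), the HOXD domains (−0.075 and −0.071, adjusted p = 0.056 and 0.0743), the protocadherin domain on chromosome 5, 140080001 to 140960000 (0.084, adjusted p = 0.106), and the IGF2 and H19 domain on chromosome 11, 1560001 to 2400000 (0.156, adjusted p = 0.0727), did not pass.

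Contacts across borders rose most at chromosome 12, 51680000 (log2 0.586, SE 0.046, limma adjusted p = 7.5e-05), just beyond KRT8 and KRT18 (51628921 to 51632952) at the end of a keratin cluster and near EIF4B. A border without annotated genes at chromosome 2, 155920000 (0.559, adjusted p = 3.84e-04) and one at chromosome 14, 24040000 (0.548, adjusted p = 1.49e-04), near PCK2, PSME1 and the granzyme genes of cytotoxic lymphocytes, followed. Separation increased most at chromosome 12, 9760000 (−0.344, adjusted p = 0.00111), in the cluster of KLR and CLEC lectin-like receptors, at chromosome 8, 58440000 (−0.317, adjusted p = 0.00195), near IMPAD1, and at chromosome 14, 57760000 (−0.297, adjusted p = 0.00965), near ARID4A and PSMA3. At the keratin border RAD21cv cells, given no CTCF siRNA, had means of −0.316 (TEV) and −0.2 (HRV). These were near siCTCF (−0.246) and above siControl (−0.832). At chromosome 12, 9760000, they (−0.485 and −0.466) were near siControl (−0.455) and above siCTCF (−0.798). At the other named borders both RAD21cv groups lay between siControl and siCTCF.

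Between TEV and HRV, 1 domain without annotated genes passed, chromosome 2, 177240001 to 177720000 (log2 0.174, SE 0.021, limma adjusted p = 0.0455), and 454 had an unadjusted p under 0.05. The median change inside domains was 0.026, with 71.6% of domains above 0. Across borders limma called 0 (297 at an unadjusted p under 0.05, smallest adjusted p = 0.108; no other tool was run), with a median of −0.023 and 36.7% above 0, which became 0.017 and 60.1% without division by expected contacts. Replicates of this line differed more than those of the siRNA groups, with an SD across domains of 0.07 for TEV and 0.077 for HRV against 0.025 for siControl and 0.024 for siCTCF. Same-numbered TEV and HRV libraries deviated alike inside domains (correlation 0.69), though the labels give no pairing. With the replicate number as a block within each cell line, 461 domains and 0 borders passed, so the count of 1 depends on ignoring these shared deviations. After iterative correction 372 domains passed, quantile normalization gave 11 (2 higher, 9 lower), and without HRV replicate 1 the count was 10, while without any other single library it was 0. Borders came to 2 without TEV replicate 1 and 18 without HRV replicate 1.

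The arms differed in 476 domains, 436 with a higher TEV minus HRV than siCTCF minus siControl change and 40 with a lower one, and in 289 borders, 20 higher and 269 lower (limma). With the protease difference taken as HRV minus TEV, 1 domain and 54 borders (11 higher, 43 lower) differed, so most of the first count required the TEV minus HRV orientation. Without siControl replicate 1 or 2, or without siCTCF replicate 1 or 2, 0 domains differed, and 19, 67, 70 and 48 borders in this order. Domains came to 314 without TEV replicate 1 and 871 without HRV replicate 1, and borders to 538 without HRV replicate 1. Quantile normalization gave 442 domains (229 higher, 213 lower) and 291 borders (140 higher, 151 lower), and without division by expected contacts 105 borders differed (23 higher, 82 lower). Across domains the changes of the arms correlated at r = −0.214 (Spearman −0.223) and across borders at −0.106 (−0.102).

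**Figure D3:**
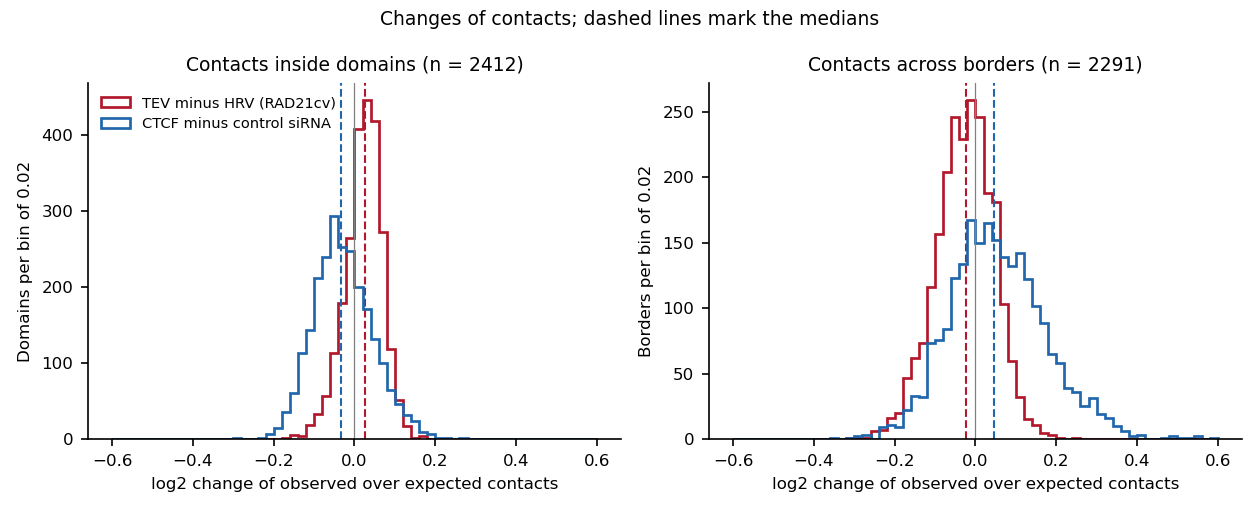
Number of domains (contacts inside) and borders (contacts across), vertical axes, by log2 change in observed over expected contacts, horizontal axes in bins of 0.02, for siCTCF minus siControl and TEV minus HRV, with dashed lines at the medians. With the CTCF siRNA the medians are −0.034 inside and 0.047 across, and for TEV minus HRV they are 0.026 and −0.023.

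In RAD21cv cells, borders were shared between groups about as often as between replicates. Called per library, there were 2714 and 2746 borders with TEV, 2696 and 2644 with HRV, 2832 and 2722 in siControl, and 2574 and 2566 in siCTCF cells. TEV and HRV libraries shared 72.68% of borders within 1 bin (69.2% to 75.2%), against 68.7% to 76.5% between replicates. siCTCF and siControl libraries shared 70.97% (68.8% to 73.5%), below the 83.2% to 83.3% between replicates. Shifted borders gave 10.9% to 11.5%. Large-scale compartments were compared without a test, and the eigenvector that defined them followed gene density only weakly, with a median correlation over chromosomes of 0.3 and a lowest of 0.159. Contacts within compartments exceeded those between them 1.2794-fold and 1.2802-fold in siCTCF against 1.3016-fold and 1.2962-fold in siControl libraries (difference −0.0191), and 1.3138-fold and 1.2978-fold with TEV against 1.297-fold in the 1 HRV library that reached 10 Mb (0.0088). Eigenvectors correlated across bins at 0.918 between siControl and 0.953 between siCTCF replicates, and at 0.863 to 0.921 between these groups. TEV replicates correlated at 0.818, and TEV with HRV at 0.859 and 0.906. Each eigenvector was chosen and signed by its correlation with that of the mean map of these libraries, so part of this agreement is built in.

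The change inside domains with the CTCF siRNA followed gene density, a property examined after the domain counts were known. Domains were ordered by genes per Mb into 4 classes of 603, with medians of 1.0, 3.7, 7.7 and 16.3 genes per Mb, and in this order the median log2 change was −0.069, −0.048, −0.022 and 0.023. Of the domains called lower, 115, 100, 57 and 26 lay in these classes, and of those called higher 6, 5, 17 and 51. For TEV minus HRV the medians were 0.015, 0.033, 0.039 and 0.017. The RAD21cv replicates also differed from each other along gene density, by −0.085 and −0.1 between the classes with most and fewest genes (replicate 1 minus 2).

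**Figure D4:**
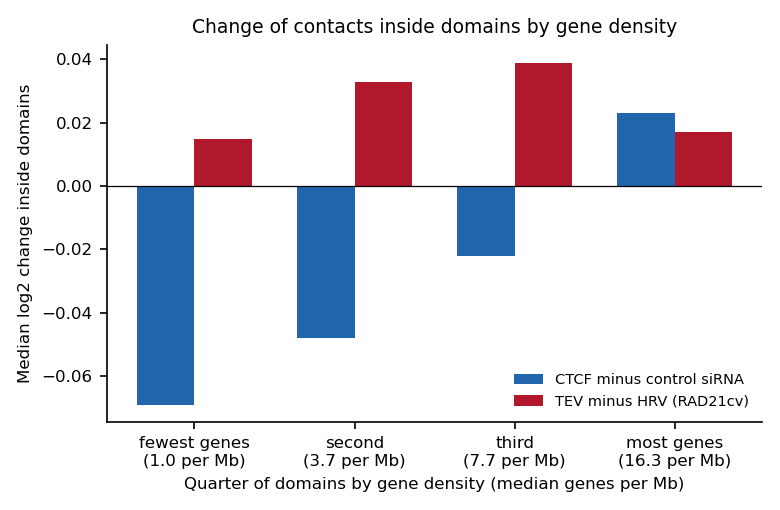
Median log2 change in contacts inside domains (vertical axis) in 4 classes of 603 domains ordered by genes per Mb (horizontal axis, medians 1.0, 3.7, 7.7 and 16.3), with bars for siCTCF minus siControl and TEV minus HRV. The siCTCF bars go from −0.069 to 0.023, and the TEV bars stay between 0.015 and 0.039.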

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

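The tests of STAG2 reads, of the whole cohesin complex, of depth, of the scaling and of library preparation were chosen after the results were seen, while those of border depth and of gene density were written down before theirs.

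With the protease difference taken as TEV minus HRV, the arms differed by a test of the difference itself in 15 genes, 476 domains and 289 borders, although cell line, agent and time after transfection differ between them as well. Taken as HRV minus TEV the counts were 13 genes, 1 domain and 54 borders. In the fit of all 8 libraries the TEV minus HRV counts fell when any siRNA library was left out. Without siControl replicate 1, siControl replicate 2, siCTCF replicate 1 and siCTCF replicate 2 in turn, they were 3, 3, 3 and 2 genes, 0 domains each time, and 19, 67, 70 and 48 borders. Without TEV replicate 1 they were 8 genes and 314 domains, without HRV replicate 1 871 domains and 538 borders, and without HRV replicate 2 64 genes. As TEV minus HRV less siCTCF minus siControl, the log2 differences were −4.35 for ZNF185, −2.47 for LOC440356, −1.82 for FDXACB1, −1.74 for STAG1, −1.42 for C17orf49, 1.78 for ADD2, 1.55 for TMC7, 1.52 for MAGT1, 1.42 for CC2D2A and 1.28 for NLRX1. For all of these but STAG1, the protease change was between −0.37 and 0.15 on the log2 scale and none passed in that arm. STAG1 did not pass as HRV minus TEV (−0.56, edgeR adjusted p = 0.233). FDXACB1, LOC440356 and C17orf49 overlap other genes and are uncertain.

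STAG1, which encodes 1 of a pair of alternative cohesin subunits, was higher with the CTCF siRNA (1.15) and lower with TEV than with HRV (−0.59, not past the threshold with edgeR). Reads exchanged with its paralog STAG2 would leave the sum of both unchanged, but the sum stood at 0.41 with the CTCF siRNA and −0.19 for TEV minus HRV, and STAG2 did not move the opposite way. A change of the whole complex is argued against by the other subunits, whose median was 0.1 with the CTCF siRNA and −0.09 for TEV minus HRV. An effect of the siRNA sequence on other transcripts was not tested, because each treatment used 1 agent, and the sign in the protease arm depends on which protease cuts RAD21.

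With the CTCF siRNA, contacts were lower inside domains and higher across borders than in siControl libraries. Depth is argued against by the siControl replicates, whose medians across borders differ by 0.006 (0.002 inside) although their shares of bin pairs above 0 at a distance of 1 Mb differ by 7.31 points, more than the 3.17 points between the groups, which differ by 0.047 across and 0.04 inside in size. Without division by expected contacts the change across borders was 0.041 and inside −0.068, so both signs stayed. This cannot clear the division, because undivided values also follow the spread of contacts over distance. The share of contacts 40 to 160 kb apart was 37.658% in siCTCF against 39.23% in siControl libraries, which by itself lowers undivided values inside domains. For a loss of separation in proportion to border depth, a positive correlation of depth in the RAD21cv libraries with the gain was looked for. The Spearman value was −0.143 over 2291 borders, with median gains of 0.086, 0.042, 0.031 and 0.035 over 4 classes of borders from weakest to strongest. This cannot decide, because the borders were called on the mean map of all 8 libraries. Borders weak in the RAD21cv libraries may thus have been kept mainly where siRNA libraries, siControl among them, separated more strongly. The authors' normalization also stays open, since its method is not known and it could act differently in the groups.

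The change inside domains with the CTCF siRNA followed gene density, with a Spearman correlation of 0.465 over 2412 domains against 0.062 for TEV minus HRV, and 0.302 after iterative correction. Domains are not independent replicates. A difference between library preparations is a candidate explanation that cannot be told apart from an effect of the siRNA. RAD21cv replicates of the same group differed by up to 0.1 in size between gene-rich and gene-poor domains, as much as the 0.091 between siCTCF and siControl, whereas replicates of the siRNA groups differed by at most 0.005. Nothing in the labels says which libraries were prepared together, which keeps this open.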

How the results depend on the processing

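The iterative correction for domains and borders, the quantile normalization of Hi-C values, DESeq2, its size factors in edgeR, limma on log2(RPKM + 1), the block within each cell line, Hi-C fits of 4 libraries alone, the opposite orientation and leaving out libraries for shared borders and compartments were added after seeing the data, and the cause was not tested where a value moved, except where fewer samples or genes entered. In simulations DESeq2 made 40 false calls among 194 for TEV against HRV and 30 among 176 for siCTCF against siControl. Those simulations gave all libraries the same dispersion for a gene, so these rates may not hold for the real libraries. Thinning was not run because Hi-C read counts are not used here, values without correction are those of the main result, the 2 Mb range was run as 1 Mb, and the sole HRV library with compartments could not be left out.

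For TEV against HRV, edgeR called 0 genes, but 5 without a filter and DESeq2 52. For siCTCF against siControl the 71 genes became 109 without a filter, 28 at a mean RPKM of at least 5, 2207 with the 4 libraries alone and 216 with DESeq2. For the difference between the arms, the 15 became 9 with limma at either pseudocount, 31 without a filter, 7 at a mean RPKM of at least 5 and 179 with DESeq2. The overlap of 0 became 2 with DESeq2. With an estimated correlation the list calls went from 14, 4 and 7 to 0, 0 and 0, and with HRV minus TEV the 7 became 14. Other scalings and a minimum change of 1.5-fold stayed within 1.5 times of these counts.

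For Hi-C domains, TEV against HRV went from 1 to 0 with a 200-kb window, 0 without expected contacts, 372 after iterative correction, 0 with the 4 libraries alone and 11 after quantile normalization. The 377 of siCTCF against siControl became 846 without expected contacts, 1004 after iterative correction, 1610 with the 4 libraries alone and 573 after quantile normalization, and the 476 of the difference became 770 without expected contacts, 1052 after iterative correction and 1 with HRV minus TEV. For borders, the 0 of TEV against HRV became 5 after iterative correction, the 443 of siCTCF against siControl 764 with a 200-kb window and 1063 with the 4 libraries alone, and the 289 of the difference 105 without expected contacts, 458 after iterative correction and 54 with HRV minus TEV. The change in the near share was −0.615 points for TEV and −1.277 for siCTCF without adjacent bins. Shared borders were 82.2% and 78.92% within 2 bins, and 68.17% and 73.9% with a 200-kb window. With 1-Mb bins the compartment difference for siCTCF was −0.0132.

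The replicate numbers are only shared between groups and give no pairing in the labels. Deviations of same-numbered RNA libraries correlated at 0.56 for TEV with HRV and 0.26 for siControl with siCTCF, and those of Hi-C domains at 0.69 and 0.05. With the replicate number as a block, genes called were 0, 104 and 24 for TEV, siCTCF and their difference, lists 13, 4 and 7, domains 3, 556 and 632, and borders 6, 517 and 370. With a block within each cell line they were 22, 290 and 334 genes, 13, 4 and 9 lists, 461, 1222 and 1162 domains, and 0, 542 and 403 borders.

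Leaving out 1 library at a time assumes that the lone sample varies like the other groups. Genes ranged over 0 to 3 for TEV (3 without TEV or HRV replicate 2), 2 to 118 for siCTCF (3, 4, 3 and 2 without siControl 1, siControl 2, siCTCF 1 and siCTCF 2, and 118 without either HRV library) and 2 to 64 for the difference (8 without TEV 1, 64 without HRV 2, and 3, 3, 3 and 2 without the siRNA libraries in that order). Domains ranged over 0 to 10 for TEV (10 without HRV 1, otherwise 0), 0 to 741 for siCTCF (741 and 730 without HRV 1 and 2, 0 without each siRNA library) and 0 to 871 for the difference (314 without TEV 1, 871 without HRV 1, 0 without each siRNA library). Borders ranged over 0 to 18 for TEV (2 without TEV 1, 18 without HRV 1), 50 to 677 for siCTCF (676 and 677 without HRV 1 and 2, and 50, 120, 110 and 98 without the siRNA libraries) and 19 to 538 for the difference (538 without HRV 1, and 19, 67, 70 and 48 without the siRNA libraries). The near share ranged over −2.24 to −0.78 points for TEV and −1.702 to −1.443 for siCTCF, shared borders over 70.2% to 75.15% and 68.95% to 73.0%, and compartments over 0.0008 to 0.0168 and −0.0218 to −0.0164.

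No named gene, domain or border passed the threshold in the opposite direction under any alternative. Among the 38 genes named for siCTCF, 385 results with other settings were on the same side of the threshold, 13 passed newly and 4 no longer passed, and with a library left out 2 passed newly and 76 no longer passed. For the 67 named for TEV, 34 results with other settings and 2 with a library left out passed newly. For the 10 named for the difference, 9 no longer passed with other settings and 42 with a library left out. For the 22 named domains and borders tested for TEV against HRV, 10 results passed newly and 2 no longer passed with other settings, and 7 no longer passed with a library left out. Tested for siCTCF against siControl, the same features gave 25 results that passed newly and 3 that no longer passed with other settings, and 16 and 31 with a library left out.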

Other observations

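The comparisons of replicates and of chromosome regions, and the test of gene-by-gene regulation, were chosen after the values were seen, while the tests of copy number, of contacts near called genes and of expression within domains were written down before their results.

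RAD21cv replicates differed in some genes in TEV and HRV alike. The single genes named here were chosen after their values were seen, and no enrichment was tested. For replicate 1 minus replicate 2, given for TEV and then HRV on the log2 scale, CHAC1, which degrades glutathione, stood at −1.17 and −1.55, the cystine transporter gene SLC7A11 at −1.8 and −1.36, asparagine synthetase ASNS at −0.9 and −1.15, PCK2 at −1.18 and −1.53, PSAT1 of serine synthesis at −0.97 and −0.98, and DDIT4 at −0.72 and −1.28. The stress response genes DDIT3 (0.14 and −0.21) and TRIB3 (−0.57 and −0.54) differed less. FOS (−1.73 and −2.28) and FOSB (−2.58 and −2.26) were lower and ATF3 (1.02 and 1.04) higher in replicate 1. The unfolded protein response list had medians of −0.44 and −0.46, with 17 and 20 of 23 genes lower, and the extracellular matrix list −0.49 and −0.43, with 18 and 19 of 20 lower. These differences between replicates were not tested.

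Gene expression in RAD21cv cells differed from that in the siRNA-treated HEK293T cells over long chromosome regions. On chromosome 3 below 90 Mb, 293 of 355 genes (82.5%) were lower in the mean of the 4 RAD21cv libraries than in that of the 4 siRNA libraries, with a median log2 difference of −0.31, against 0.04 on the rest of the chromosome. On X below 80 Mb, 199 of 208 genes (95.7%) were lower, with a median of −0.73 against −0.16 beyond. The 11502 genes of other chromosomes had a median of 0.02. Line, transfected agent and time differ together here, and SE or p-values were not computed.

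Regulation gene by gene, independent of neighbours, would scatter lower genes over the genome. Instead, 14 of 282 windows of 10 Mb had a median below −0.3, 13 of them on chromosomes 3 and X. The most in 1000 random placements of the genes was 2. These placements break up neighbours and were made after the regions were seen, so they cannot exclude regulation that neighbouring genes share. A hypothesis is that the RAD21cv line carries fewer copies of these regions. If so, Hi-C values per bin might be lower there by at least 0.2, but they were higher in RAD21cv libraries, by 0.103 on chromosome 3 below 90 Mb relative to its rest and by 0.199 on X below 80 Mb, where chromosomes 4, 5, 6 and 7, split likewise, gave 0.025 to 0.055. The deposited values were normalized by a method that is not known and that can remove or overturn differences in copy number, so fewer copies and another regional difference between the lines cannot be told apart.

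A second hypothesis was that genes called with the CTCF siRNA lie where contacts changed. The nearest border had changed for 17 of 56 called genes (30.4%, exact 95% interval 18.8% to 44.1%) against 2310 of 9929 genes tested (23.3%; Fisher's exact p = 0.207). The domain holding the gene had changed for 8 of 55 (14.5%, 6.5% to 26.7%) against 1339 of 9933 (13.5%; Fisher's exact p = 0.842). By the rule written down beforehand, a share below 1.5 times that of all genes tested counted against the hypothesis, and both shares were below. Both intervals include the 1.5-fold excess looked for as well as no excess, so the 71 called genes may be too few to decide. Over 1139 domains with at least 3 tested genes, the change inside correlated with the mean expression change at a Spearman value of −0.108, and at −0.05 with gene density held, which leaves open a weak relation or none. The value of −0.108 just met the size written down beforehand for a relation. The value with gene density held, which that rule did not name, was below this size.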
